A study of Mus musculus with 4 samples.

How the data were processed

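RNA from mouse osteoblasts was measured on Affymetrix arrays with a 3′ in vitro transcription labelling, per the labels. The labels give 4 groups with 1 array each, namely a control at 0 h and cells given 10 nM insulin for 6, 12 and 24 h. Per the labels' protocols the cells were grown to confluence and serum-starved before insulin, and RNA was extracted with Trizol and checked for integrity. The growth protocol names a missing IGF-1 receptor, while the genotype entry names IGF-1. Which is meant is not settled by the sources used here.

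The deposited table held 1 intensity per probe set and array on a linear scale, and the submitters' processing notes name RMA, a method that corrects background, normalizes arrays to one another and summarises probes on the log scale. Its software, its version and the genome build are not given in the sources used here. The values ran from 7.34 to 31292, so they were read as RMA values returned from the log scale, and log2 was taken before any comparison. The sorted columns were close but not identical, with gaps of up to 0.179 log2 to the 0 h array. The probe set values were therefore not taken to be exactly quantile normalized. RMA normalizes before it summarises probes, so the gaps do not speak against that step. RMA compresses differences of dim probe sets, and values near background set the folds of genes that were almost silent on 1 array. Signal over background limits what can be seen. The median intensity of all probe sets that are not controls, averaged over arrays, was 66.2, and probe sets below it were left out of the main counts.

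Of 45101 probe sets 64 were controls. The platform annotation given for this work named 1 gene symbol for 34958 probe sets, several for 932 and none here for 9147. The 34958 named 18194 genes. The annotation can be old. Each gene was represented by its probe set with the highest mean over the 4 arrays. Genes whose representative reached the brightness filter were kept, which left 11662. For 7206 genes there were several probe sets, and the text says where another one above the filter pointed the other way. A RefSeq gene table of the mouse assembly GRCm38.p6 was used only for chromosomes and the order of genes, and 11647 of the kept genes had a symbol in it.

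With 1 array per group no test between groups is possible, and no p-value, standard error or standard deviation of a difference is given. The log2 intensity of the 0 h array was subtracted from that of each insulin array, and genes at least 2-fold higher or lower were counted. Genes past that size at all 3 times were counted, and the same count was made with each other array in place of the 0 h array. Gene lists of pathways, responses and cell type markers were fixed before the data were examined, 28 in all with 597 entries, of which 38 had no probe set with 1 symbol. For each list the median log2 difference over members above the filter was set among the medians of 10000 random lists of the same size, matched on deciles of mean expression. Members at least 1.5-fold higher or lower were counted. The percentile describes these arrays and is not a test of insulin. Genes to be named were also set by a rule fixed before the data were examined. They were the 10 largest positive and 10 largest negative differences at each time, a set of genes of the insulin and IGF system, bone and reference genes, and up to 4 members of each list with the largest difference of at least 1.5-fold. Predicted transcripts were passed over, and 1 gene that this rule names among the largest negative differences is not reported here. Sex-linked genes, chromosomes and comparisons between insulin arrays were chosen after the data were seen, as were the genes named for them.

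The counting steps were tested on simulated data for 11662 genes. All 4 simulated arrays were built from the mean of the insulin arrays, with noise set by the 24 h minus 12 h differences. All of 100 genes changed 3-fold and 0 of 100 changed 1.5-fold were recovered at the 2-fold threshold in each comparison. No unchanged gene was called, also for all 3 times together. With so little noise this checks the counting steps and not the error of differences from the 0 h array. Of 200 random lists without a change, 4.5% fell outside the central 95%. Their genes were drawn at random with independent noise, so this does not check percentiles of lists whose members move together. The alternatives were other fold thresholds, other brightness filters, median centring, quantile normalization, removal of a loess curve with a span of 0.3, other rules for genes with several probe sets, means in place of list medians, and other arrays as the reference. Chromosome medians removed, sex chromosome genes left out and insulin arrays as the reference were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.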

Results

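Gene expression was measured in cultured mouse osteoblasts, the bone-forming cells, during a time course with insulin. Per the labels the cells lacked the IGF-1 receptor, the growth factor receptor most closely related to the insulin receptor, although the genotype entry names the ligand IGF-1 instead. The cells were serum-starved and given 10 nM insulin for 6, 12 or 24 h, and a control array was labelled 0 h. The series holds 4 arrays with 1 array in each group, so there are no replicates. Differences below are between single arrays, without a p-value or an error, and the number of arrays limits the precision. No untreated array later than 0 h was analysed here, so time in culture and insulin go together. Each array gave an intensity for 45037 probe sets and 64 controls, and the median intensities of the 4 arrays lay between 64.97 and 65.75. After a filter on brightness 11662 named genes were compared.

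Both genes that the labels name as missing were read first, with the insulin receptor. The brightest Igf1r probe set had intensities of 388, 259, 265 and 319 at 0, 6, 12 and 24 h. A second Igf1r probe set above the filter was lower on the insulin arrays as well (191, 149, 152 and 152), and another pointed the other way (74.7, 139, 119.8 and 119). Igf1, the ligand named in the genotype entry, was bright on all 4 arrays (1641, 5532, 5983 and 6024), and each of its 4 probe sets was higher on the insulin arrays. Where these probe sets lie relative to any deleted part of either gene is not given in the sources used here, so the signals check neither genotype. Insr, the insulin receptor, had intensities of 369, 181, 206 and 215, which is 2.04, 1.80 and 1.71-fold lower at 6, 12 and 24 h than at 0 h.

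By the labels, the comparison of each insulin array with the 0 h array sets insulin-treated cells against the control. Both lack the IGF-1 receptor by the growth protocol. Sex-linked transcripts and chromosome medians, given below, also set the 0 h array apart. At 6 h, 1232 genes were at least 2-fold higher and 539 at least 2-fold lower than at 0 h. The counts were 1364 and 619 at 12 h and 1300 and 562 at 24 h. IGF-binding protein, bone matrix, cartilage, contractile and macrophage genes were among the higher ones, and interferon-stimulated and DNA replication genes among the lower ones. A set of 1144 genes was higher and 443 lower at all 3 times, against 16.1 and 1.38 for independent lists of these sizes. Because the 3 differences share the 0 h array, the same count was made with every other array in its place. No gene was 2-fold apart on all 3 remaining arrays from the 6 h, the 12 h or the 24 h array. Directly between insulin arrays, 3 genes were 2-fold higher and 2 lower at 12 h than at 6 h, 50 and 0 at 24 h than at 6 h, and 1 and 0 at 24 h than at 12 h.

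**Figure D1:**
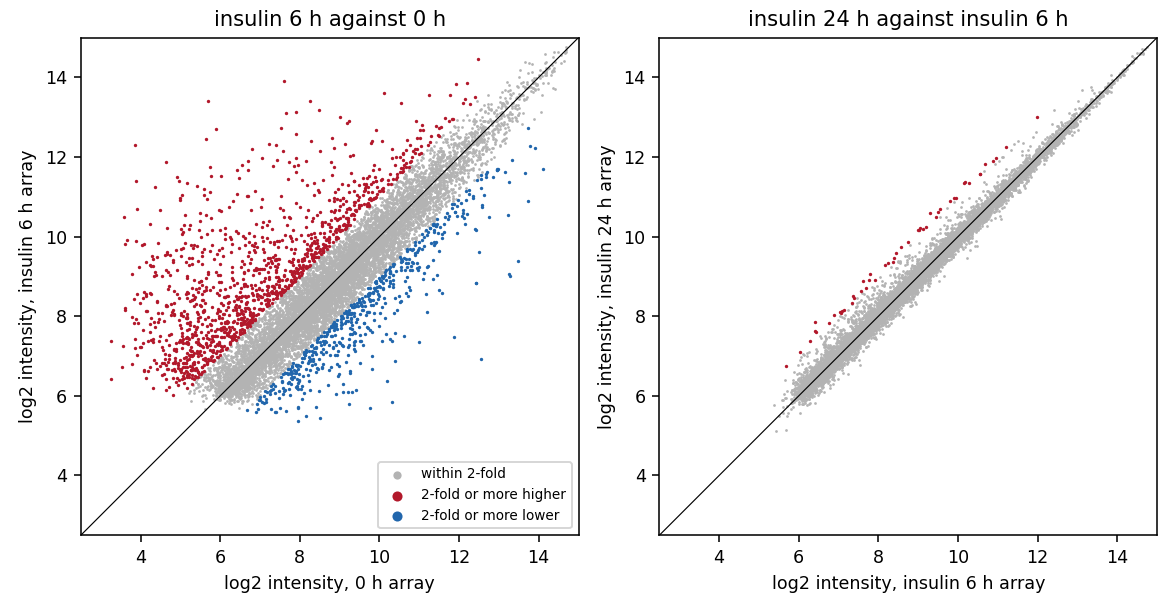
Log2 intensity of 11662 genes on 2 pairs of arrays, with each point 1 gene and the diagonal marking equal intensity. The insulin 6 h array had 1232 genes 2-fold or more above and 539 below the 0 h array (left), and the insulin 24 h array had 50 above and 0 below the insulin 6 h array (right).

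The 0 h array also differed from the insulin arrays in sex-linked transcripts and in the medians of whole chromosomes. The Y-linked gene Eif2s3y had an intensity of 12.2, 295, 305 and 326 at 0, 6, 12 and 24 h. The Y-linked genes Kdm5d and Uty had no probe set above the brightness filter. The brightest had 10.1, 57.8, 52.7 and 61.8 for Kdm5d and 12.9, 43.7, 48.7 and 52.6 for Uty. The other probe sets of these 3 genes were below the filter and less than 2-fold from 0 h. Xist, the RNA of the inactive X chromosome, had 109, 1636, 1278 and 1463. Log2 differences averaged over the insulin arrays had a median of 0.33 on chromosome 4 and 0.27 on chromosome 1, and of -0.24 on chromosome 8 and -0.22 on chromosome 3. The standard deviation of these medians over chromosomes was 0.173, against at most 0.0411 when gene positions were permuted 1000 times. For the 24 h array minus the 6 h array it was 0.00837, and 153 of 1000 permutations were as large. These measurements stand beside every gene group described against 0 h. An insulin effect within those differences cannot be separated with these arrays from whatever else set the 0 h array apart. The chromosomes and the sex-linked genes were looked at after the results were seen.

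**Figure D2:**
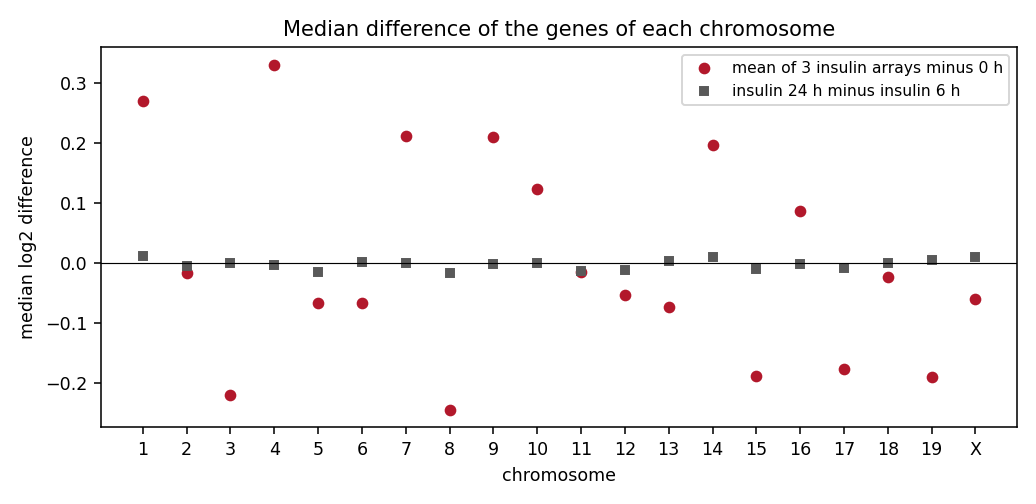
Median log2 difference of the genes of each chromosome for the mean of the 3 insulin arrays minus the 0 h array (circles) and for the insulin 24 h array minus the insulin 6 h array (squares). The circles spread from -0.24 on chromosome 8 to 0.33 on chromosome 4, and the standard deviation over chromosomes is 0.173 for circles and 0.00837 for squares.

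The genes named for the largest positive differences were below the brightness filter value at 0 h. C1qtnf3, a secreted protein of the C1q and TNF-related family, had an intensity of 14.6 at 0 h and 5035, 6194 and 5905 at 6, 12 and 24 h. Igfbp2, an IGF-binding protein, went from 52.0 to 10897, 11829.9 and 10483, and Igfbp5 from 54.9 to 2916, 4338 and 5414. Tenm3, a transmembrane teneurin, was 182, 188 and 186-fold higher at the 3 times and Sulf1, an extracellular sulfatase acting on heparan sulfate, 149, 143 and 139.7-fold. The receptor tyrosine kinase Epha3 was 120.1, 95.3 and 113-fold higher and the ribosomal protein S4-like gene Rps4l 118, 118 and 109-fold. Grb10, an adaptor that binds the insulin receptor, had 49.6, 5596, 5434 and 5438 at 0, 6, 12 and 24 h. The tendon glycoprotein gene Tnmd was 112, 129 and 103-fold higher, the transcription factor gene Zic1 110.3, 94.1 and 94.1-fold and the smooth muscle actin gene Actg2 95.6, 103 and 90.6-fold. Car3, a carbonic anhydrase, was 48.9, 84.4 and 102-fold higher. For genes this close to background at 0 h the fold is set mainly by the low value.

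Among the genes with the largest negative differences, those named here were bright at 0 h. Dlk1, a transmembrane inhibitor of adipocyte differentiation, had 11384, 674, 693 and 648 at 0, 6, 12 and 24 h, and the transporter gene Slc35e3 had 9761, 538, 615 and 613. Osr2, a zinc finger transcription factor gene, was 16.8, 20.1 and 24.5-fold lower at the 3 times. The interferon-induced gene Ifi27l2a was 19.3, 14.9 and 22.9-fold lower and Trim30a 11.5, 15.8 and 13.0-fold. The aldo-keto reductase gene Akr1c14 was 21.9, 13.8 and 15.9-fold lower, the corneodesmosin gene Cdsn 21.2, 14.0 and 11.7-fold, and the protocadherin gene Pcdhb16 14.0, 14.3 and 13.7-fold. The amino acid transporter gene Slc38a4 was 12.5, 14.2 and 13.1-fold lower, D6Wsu163e 12.0, 11.9 and 12.6-fold and Plac8 11.9, 12.4 and 15.2-fold.

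Gene lists fixed before the data were examined were then compared, each by its median log2 difference from 0 h and by the percentile of that median among 10000 random lists of the same size and expression. Of 28 lists, 11, 11 and 12 lay above the central 95% of random lists at 6, 12 and 24 h, and 8, 6 and 6 lay below.

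**Figure D3:**
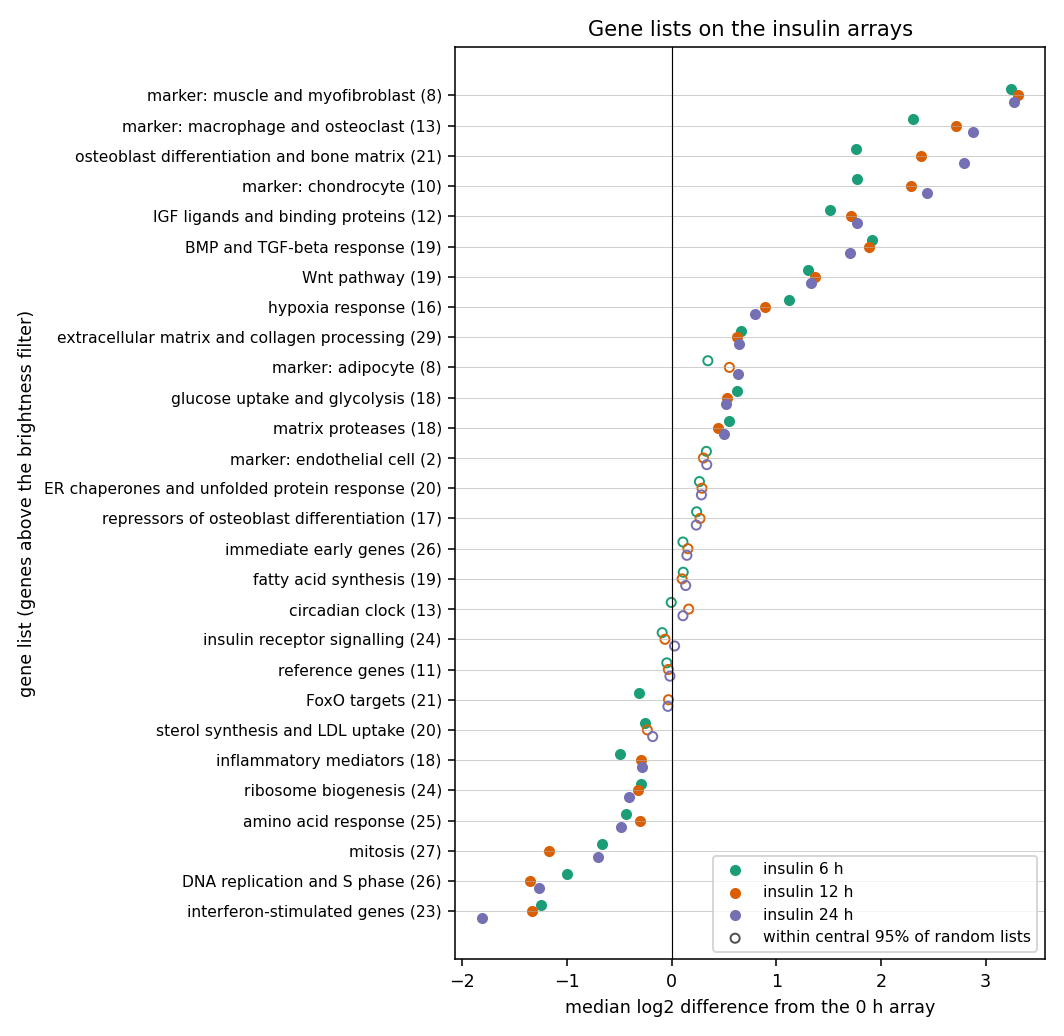
Median log2 difference from the 0 h array for each of 28 gene lists at 6, 12 and 24 h of insulin, with the number of genes in parentheses. Filled points lie outside the central 95% of 10000 matched random lists and open points inside. Over genes above the brightness filter the muscle and myofibroblast list had the largest medians (3.24, 3.31 and 3.27). The interferon-stimulated list had the lowest at 24 h (-1.81). Without the filter the muscle medians were 0.67, 0.51 and 0.54, below those of the macrophage list (1.79, 2.40 and 2.42).

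Osteoblast differentiation and bone matrix genes were higher on the insulin arrays. Of 21 measured, 15, 16 and 16 were at least 1.5-fold higher than at 0 h at 6, 12 and 24 h, and 1, 1 and 2 at least 1.5-fold lower. The list medians of 1.76, 2.38 and 2.79 lay above all 10000 random lists. Ibsp, which encodes bone sialoprotein, had 202, 8849, 11706 and 13147 at 0, 6, 12 and 24 h. Alpl, the alkaline phosphatase of mineralising cells, had 61.5, 523, 919.7 and 1139.5, and Sp7, the transcription factor osterix, had 60.8, 125, 161 and 213. Pth1r, the parathyroid hormone receptor, was 19.02, 32.1 and 39.1-fold higher, and Tnfrsf11b, the decoy receptor osteoprotegerin, 19.7, 30.4 and 34.2-fold. Both probe sets of Tnfsf11, the ligand RANKL, were below the brightness filter, and the brighter had 23.6, 67.2, 78.9 and 81.1. Col1a1, a chain of type I collagen, had 13802, 21001, 23827 and 23754 by its brightest probe set, while its other probe set pointed the other way (3149, 1507, 1825 and 1905). Without the brightness filter the list median at 24 h was 1.81, and with the mean of all probe sets the medians were 1.91, 2.04 and 1.93, so a larger median at 24 h than at 12 h depended on the probe set rule.

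**Figure D4:**
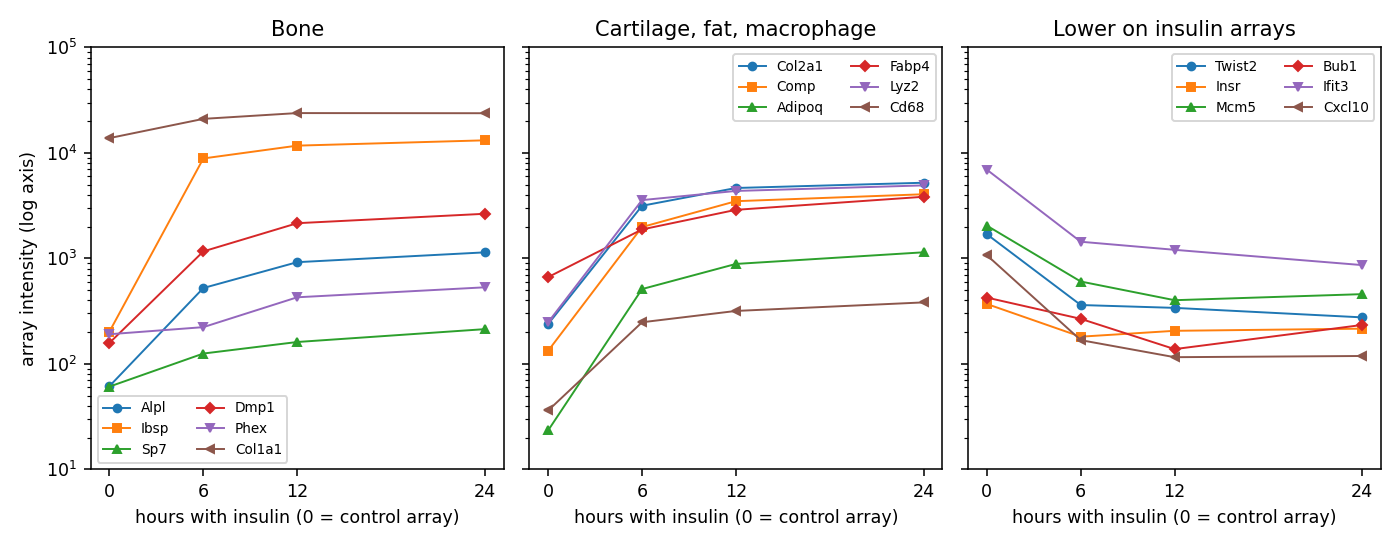
Array intensity on a log axis for 6 bone genes, 6 genes of cartilage, fat and macrophages, and 6 genes that were lower on the insulin arrays, each line 1 gene and each point 1 array. Alpl reads 61.5, 523, 919.7 and 1139.5 at 0, 6, 12 and 24 h and Twist2 1691, 361, 339 and 276; for Col1a1 the brightest probe set is drawn, and its other probe set was lower on the insulin arrays than at 0 h.

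Repressors of osteoblast differentiation did not move together. Twist2, a basic helix-loop-helix repressor of osteoblast differentiation, was the member farthest from 0 h, with 1691, 361, 339 and 276 at 0, 6, 12 and 24 h by its single probe set. That is 4.69, 4.99 and 6.14-fold lower. The related gene Twist1 had 649.8, 766, 1013 and 809. Hes1, a target of Notch signalling, was 2.10, 2.06 and 1.83-fold higher, the corepressor gene Tle1 1.96, 1.61 and 1.61-fold and the ubiquitin ligase gene Smurf2 1.61, 1.68 and 1.72-fold. Of 17 members 4, 7 and 5 were at least 1.5-fold higher at the 3 times and 1, 2 and 1 lower. The medians of 0.24, 0.27 and 0.23 were at percentiles 92, 90.1 and 90.6. With chromosome medians removed the 24 h median was 0.36, at percentile 98.45.

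Genes of the IGF system were higher, and genes of insulin receptor signalling were mixed. Of 12 IGF ligands and binding proteins, 9, 8 and 8 were at least 1.5-fold higher at the 3 times and none was 1.5-fold lower. Their medians of 1.51, 1.71 and 1.77 lay above all random lists, and with suffixed probe sets left out they were 1.09, 1.04 and 1.05. Besides Igfbp2 and Igfbp5, Igfbp3 was 34.8, 48.4 and 38.5-fold higher and Pappa, a protease that cleaves IGF-binding proteins, 17.9, 18.1 and 17.6-fold. Of 24 insulin receptor signalling genes, 3, 4 and 4 were 1.5-fold higher and 3, 3 and 3 lower, with medians of -0.09, -0.06 and 0.03 at percentiles 15.4, 17.5 and 52.1. The means over these members were 0.20, 0.27 and 0.26, which differ in sign from the medians at 6 and 12 h. Grb10 stood out as given above, Grb14 was 1.998, 2.05 and 2.15-fold higher, and Pik3r2, a regulatory subunit of PI 3-kinase, was 2.29, 2.16 and 2.46-fold lower.

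Genes of BMP and TGF-beta response, the Wnt pathway and the extracellular matrix were higher on the insulin arrays. Of 19 BMP and TGF-beta response genes 17, 17 and 18 were at least 1.5-fold higher and none was lower at that size, with medians of 1.91, 1.88 and 1.70. Id3, an inhibitor of helix-loop-helix factors induced by BMP, was 23.7, 28.9 and 23.6-fold higher, the pseudoreceptor gene Bambi 7.23, 10.3 and 10.8-fold, Tgfb3 6.75, 7.54 and 6.76-fold and Ltbp2 4.96, 6.18 and 6.80-fold. Of 19 Wnt pathway genes 12, 13 and 14 were higher and 1, 1 and 1 lower, with medians of 1.30, 1.37 and 1.33. The members farthest apart were the secreted Wnt antagonist genes Sfrp1 (34.6, 40.2 and 39.8-fold, with another probe set pointing the other way), Dkk3 (38.0, 34.7 and 32.5-fold) and Wif1 (9.01, 20.1 and 24.5-fold), and the Wnt potentiator gene Rspo3 (23.2, 27.5 and 23.3-fold). Without the filter the Wnt medians were 0.83, 0.99 and 0.93. Of 29 matrix and collagen-processing genes 15, 16 and 15 were higher and 0, 1 and 1 lower, with medians of 0.66, 0.62 and 0.64. Fmod, the collagen-binding fibromodulin, was 36.5, 51.4 and 55.4-fold higher, the lysyl hydroxylase gene Plod2 15.2, 14.97 and 17.6-fold, the tenascin gene Tnc 12.7, 12.4 and 12.5-fold and the thrombospondin gene Thbs1 11.2, 11.6 and 11.2-fold. Their 3 lists lay above at least 99.99% of random lists at each time.

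Matrix proteases and their inhibitors went both ways. Of 18, 8, 8 and 8 were at least 1.5-fold higher and 6, 6 and 6 lower, and the medians of 0.54, 0.44 and 0.50 were at percentiles 99.9, 99.2 and 99.8. The inhibitor gene Timp3 was 8.65, 10.4 and 9.23-fold higher, the collagenase gene Mmp13 4.79, 7.85 and 8.66-fold and the stromelysin gene Mmp3 2.77, 4.18 and 5.28-fold, while the gelatinase gene Mmp9 was 4.76, 4.87 and 4.64-fold lower. With the mean of all probe sets the median at 12 h was at percentile 97.2.

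Glycolysis and hypoxia genes were higher. Of 18 genes of glucose uptake and glycolysis, 9, 9 and 9 were at least 1.5-fold higher and 1, 1 and 1 lower, with medians of 0.62, 0.53 and 0.52 at percentiles 100, 99.7 and 99.8. The lactate exporter gene Slc16a3 was 10.0, 6.72 and 6.83-fold higher, Pfkfb3, which makes an activator of phosphofructokinase, 5.74, 6.16 and 4.96-fold, Aldoc 3.29, 4.29 and 4.42-fold and Pfkl 2.61, 2.23 and 2.17-fold. With the mean of all probe sets the glycolysis medians at 12 and 24 h were 0.29 and 0.31, at percentiles 94.6 and 97.4. With suffixed probe sets left out they were at percentiles 96.2 and 97.4. Of 16 hypoxia response genes 10, 10 and 10 were higher and 1, 1 and 1 lower, with medians of 1.12, 0.89 and 0.80 at percentiles 100, 100 and 100. Car9, a carbonic anhydrase induced by low oxygen, was 4.95, 7.13 and 7.13-fold higher, Ndrg1 3.42, 3.66 and 3.38-fold, Adm 3.15, 3.597 and 2.96-fold and Bnip3 3.57, 2.57 and 2.60-fold. The hypoxia list shares 3 genes with other lists of this set.

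Both lists of lipid synthesis genes leaned one way at all times, in opposite directions. Of 20 sterol genes 15, 14 and 16 were lower by any amount and 5, 6 and 4 higher. Of 19 fatty acid genes 11, 14 and 15 were higher by any amount and 8, 5 and 4 lower. Of 20 genes of sterol synthesis and LDL uptake, 1, 1 and 1 were at least 1.5-fold higher and 2, 5 and 5 lower at the 3 times, and the medians of -0.26, -0.23 and -0.18 were at percentiles 2.16, 2.91 and 8.98. With a loess curve removed the 6 h median was at percentile 3.69, and the 12 h median was at 2.09 with the mean of all probe sets and at 2.38 with suffixed probe sets left out. Fdps, a farnesyl diphosphate synthase gene, was 2.05, 2.30 and 2.25-fold lower, Idi1 1.34, 1.78 and 1.49-fold, Sqle 1.60, 1.64 and 1.73-fold and Stard4 1.49, 1.69 and 1.69-fold. Of 19 fatty acid synthesis genes 5, 5 and 5 were higher and 2, 2 and 2 lower, with medians of 0.11, 0.10 and 0.13 at percentiles 69.8, 60.6 and 76.5. With the mean of all probe sets the 6 h fatty acid median was -0.0515. Malic enzyme Me1 was 4.75, 5.23 and 5.48-fold higher, Srebf1, which encodes the transcription factor SREBP1, 1.82, 2.16 and 1.97-fold, and the desaturase gene Scd1 1.54, 2.21 and 2.57-fold with another probe set pointing the other way. Acsl4 was 1.64, 2.08 and 1.64-fold lower.

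FoxO targets, amino acid response and ribosome biogenesis genes had medians below 0, those of FoxO targets at 12 and 24 h close to it, and chaperone genes had medians above 0. FoxO factors are inactivated by insulin in many cells. Of 21 FoxO targets 4, 4 and 5 were at least 1.5-fold higher and 6, 6 and 5 lower, with medians of -0.31, -0.03 and -0.04 at percentiles 0.47, 27.8 and 35.3. The cell-cycle inhibitor gene Cdkn1b was 2.87, 3.41 and 2.74-fold lower, Txnip 2.26, 1.998 and 2.18-fold and Btg1 2.13, 2.02 and 1.86-fold, while Klf4 was 1.80, 2.10 and 1.98-fold higher. Without the filter the 6 h median of this list was -0.03, at percentile 38.7. Of 25 amino acid response genes 3, 3 and 3 were higher and 8, 8 and 10 lower, with medians of -0.43, -0.30 and -0.49, at percentiles 0, 0.24 and 0. Gpt2 was 2.67, 2.20 and 2.34-fold lower, the serine synthesis gene Psat1 2.03, 2.02 and 2.42-fold and Cth 1.94, 1.76 and 2.11-fold, while the stress gene Nupr1 was 2.46, 2.92 and 2.85-fold higher. Of 24 ribosome biogenesis genes none was 1.5-fold higher and 5, 7 and 8 were lower, with medians of -0.29, -0.33 and -0.41 at percentiles 0.34, 0.16 and 0.05. Dkc1, the pseudouridine synthase dyskerin, was 2.06, 2.47 and 2.22-fold lower, Nip7 2.07, 2.22 and 2.38-fold, Nolc1 1.76, 1.87 and 2.01-fold and Nop58 1.35, 1.95 and 1.39-fold. Of 20 chaperones and unfolded protein response genes 5, 5 and 4 were higher and 1, 1 and 1 lower, with medians of 0.26, 0.29 and 0.28 at percentiles 93.8, 93.6 and 95.3. Dnajc3 was 2.79, 2.72 and 2.77-fold higher, Manf 2.16, 1.87 and 1.78-fold and Dnajb9 1.99, 2.07 and 2.03-fold, and Herpud1 was 1.68, 1.57 and 1.67-fold lower.

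Genes of DNA replication and mitosis were lower on the insulin arrays. Of 26 replication and S phase genes none was 1.5-fold higher and 20, 22 and 22 were lower, with medians of -1.002, -1.36 and -1.27 below all 10000 random lists. The replication licensing gene Cdt1 was 3.898, 5.25 and 4.85-fold lower, the helicase subunit genes Mcm5 3.38, 5.09 and 4.46-fold and Mcm6 3.31, 5.06 and 4.43-fold, and Cdc6 3.19, 3.50 and 4.05-fold. Of 27 mitosis genes none was 1.5-fold higher and 17, 27 and 17 were lower, with medians of -0.67, -1.17 and -0.70, also below all random lists. The spindle motor gene Kif11 had 233, 95.6, 72.0 and 97.3 at 0, 6, 12 and 24 h, and the checkpoint kinase gene Bub1 had 425, 267, 138 and 234. Cenpe was 2.11, 3.07 and 2.11-fold lower and the cyclin gene Ccna2 2.03, 3.06 and 2.16-fold.

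Interferon-stimulated genes were lower, farthest at 24 h. Of 23 measured, 17, 17 and 20 were at least 1.5-fold lower at 6, 12 and 24 h and 1, 1 and 0 higher, with medians of -1.25, -1.34 and -1.81 below all random lists. Cxcl10, a chemokine induced by interferon, was 6.39, 9.27 and 9.03-fold lower, the antiviral gene Rsad2 7.03, 7.63 and 8.64-fold, Oasl2 5.29, 4.58 and 8.15-fold and Ifit3 4.82, 5.75 and 8.03-fold. Inflammatory mediators split. Of 18, 6, 6 and 6 were at least 1.5-fold higher and 9, 7 and 8 lower. Their medians of -0.49, -0.29 and -0.28 were at percentiles 0.01, 1.11 and 2.13, and the means of 0.19, 0.38 and 0.36 had the opposite sign. Without the filter the medians were at percentiles 27.0, 7.74 and 3.52. The adhesion molecule gene Icam1 was 10.7, 16.2 and 16.9-fold higher, the lipocalin gene Lcn2 4.302, 9.15 and 10.3-fold, Ptgs2, the inducible cyclooxygenase, 9.08, 7.44 and 8.87-fold, and Il6 5.02, 5.34 and 4.93-fold.

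Markers of other cell types were higher on the insulin arrays than at 0 h. Of 13 macrophage and osteoclast markers 11, 12 and 12 were at least 1.5-fold higher and 1, 1 and 1 lower, with medians of 2.30, 2.72 and 2.88. The lysosomal protease gene Ctss had 51.0, 1079, 1601 and 1721 at 0, 6, 12 and 24 h, and the lysozyme genes Lyz1 and Lyz2 had 512, 8269.7, 9456 and 10907 and 248, 3565, 4354 and 4914. Laptm5 was 15.5, 25.8 and 31.3-fold higher, with another probe set pointing the other way. Of 10 chondrocyte markers 7, 9 and 9 were higher and 0, 0 and 0 lower, with medians of 1.77, 2.28 and 2.44. Col2a1, the main collagen of cartilage, had 239, 3151, 4643 and 5209, and Comp, a cartilage matrix protein, 133, 1980.4, 3481 and 4051. Col9a1 was 8.16, 14.2 and 15.8-fold higher and Col10a1, the collagen of hypertrophic cartilage, 4.96, 7.47 and 8.66-fold. Of 8 muscle and myofibroblast markers 7, 7 and 7 were higher and 0, 0 and 0 lower, with medians of 3.24, 3.31 and 3.27. Besides Actg2, the smooth muscle genes Tagln and Cnn1 were 80.0, 82.0 and 77.3-fold and 72.5, 80.7 and 73.8-fold higher, and Acta1 13.2, 13.8 and 12.5-fold. These 3 lists lay above all random lists. With the mean of all probe sets the macrophage medians were 1.40, 1.74 and 1.95. Without the filter, which adds dim genes, the muscle medians were 0.67, 0.51 and 0.54.

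Of 8 adipocyte markers 4, 4 and 4 were at least 1.5-fold higher and 2, 1 and 1 lower at the 3 times. Their medians of 0.35, 0.55 and 0.64 were at percentiles 93.1, 97 and 98.5. Adipoq, the adipocyte hormone adiponectin, had 23.4, 511, 885 and 1141 at 0, 6, 12 and 24 h, the fatty acid binding protein gene Fabp4 had 664, 1879, 2883 and 3834, and Cd36 was 5.91, 8.06 and 9.72-fold higher. The lipoprotein lipase gene Lpl was 6.39, 3.98 and 3.14-fold lower. With suffixed probe sets left out the medians were -0.0889, -0.17 and -0.12, and without the filter they were -0.0653, -0.0247 and 0.25, so the direction of this list depended on the processing. Only 2 endothelial markers passed the filter, with medians of 0.33, 0.30 and 0.33 at percentiles 71.9, 67 and 70.3. The member farthest from 0 h was Egfl7, 1.43, 1.70 and 1.59-fold higher.

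Against 0 h, immediate early, clock and reference genes lay inside the central 95% of random lists at all 3 times. Of 26 immediate early genes 8, 8 and 9 were at least 1.5-fold higher and 2, 3 and 4 lower, with medians of 0.11, 0.15 and 0.14 at percentiles 82.2, 84.8 and 88.7. The matricellular genes Ccn2 and Ccn1 were 35.9, 42.5 and 41.3-fold and 5.98, 7.33 and 6.28-fold higher, the phosphatase gene Dusp6 3.21, 3.56 and 3.14-fold and Fos 2.45, 2.86 and 2.22-fold. The means of this list, 0.46, 0.49 and 0.47, were over 3 times the medians at each time. Of 13 clock genes 2, 3 and 1 were higher and 0, 0 and 0 lower, with medians of -0.00, 0.16 and 0.11 at percentiles 48.5, 75.2 and 72.1. Nfil3 was 1.71, 1.82 and 1.81-fold higher, Arntl 1.62, 1.12 and 1.17-fold, Cry2 1.23, 1.55 and 1.23-fold and Nr1d1 1.20, 1.51 and 1.34-fold. Of 11 reference genes 1, 1 and 1 were higher and 1, 0 and 2 lower, with medians of -0.05, -0.03 and -0.02 at percentiles 25.4, 28 and 35.1. Actb, with 21418, 25455, 24661 and 24741 at 0, 6, 12 and 24 h, and Gapdh, both represented by control probe sets, lay within 1.5-fold of 0 h, while another Actb probe set (372, 269.96, 344 and 382) pointed the other way at 6 and 12 h. Hprt was 1.84, 1.56 and 1.62-fold higher, B2m 1.54, 1.47 and 1.51-fold lower and Tbp 1.27, 1.30 and 1.51-fold lower.

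Because the insulin arrays resembled one another far more than the 0 h array, they were also compared among themselves, a comparison chosen after the data were seen. Pearson correlations of log2 intensity were 0.997, 0.997 and 0.998 between insulin arrays and 0.954, 0.949 and 0.950 with 0 h. At 24 h, 196 genes were at least 1.5-fold higher and 14 lower than at 6 h, and at 12 h, 133 and 39. Genes of mature bone cells were among the higher ones. Phex, a peptidase of osteocytes, had 223 at 6 h and 531 at 24 h, Dmp1, a matrix protein of osteocytes, 1164 and 2645, and Alpl 523 and 1139.5. Wif1 was 2.71-fold higher at 24 h, Esm1 2.46-fold, Lcn2 2.40-fold, Panx3 2.18-fold and Adipoq 2.23-fold. Of 21 bone genes 8 were at least 1.5-fold higher at 24 h than at 6 h, with a median of 0.27. The numbers were 7 of 10 for chondrocyte, 6 of 8 for adipocyte and 4 of 13 for macrophage markers, with medians of 0.67, 0.80 and 0.55. All 4 medians lay above all random lists, and none of these genes was 1.5-fold lower.

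Interferon-stimulated genes were lower at 24 h than at 6 h in 22 of 23 cases, with a median of -0.37. Usp18 was 1.70-fold lower and Ifit3 1.67-fold. Hypoxia genes were lower in 14 of 16 cases with a median of -0.22, and FoxO targets higher in 19 of 21 with a median of 0.15, which was 0.0648 without the filter. Mitosis genes dipped at 12 h. The median was -0.54 at 12 h against 6 h, with 26 of 27 genes lower, and 0.45 at 24 h against 12 h, with 27 of 27 higher. Bub1 had 267, 138 and 234 at 6, 12 and 24 h, Mki67 had 525, 365 and 601 and Top2a had 641, 466 and 724. All 25 measured amino acid response genes were lower at 24 h than at 12 h, with a median of -0.18. Each of these medians lay above or below all 10000 random lists. At 24 h against 6 h, however, 9 of 28 lists lay above the central 95% of random lists and 7 below. The numbers were 11 and 7 at 12 h against 6 h, and 9 and 3 at 24 h against 12 h. Insulin receptor signalling, with a median of only 0.07 at 24 h against 6 h, was at percentile 99.27. Members of a list can move together, unlike genes drawn at random, so percentiles between insulin arrays do not measure the strength of a change.

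Differences that share no array were compared across genes, which are not independent replicates. For noise alone these correlations are near 0. The 6 h minus 0 h difference correlated at -0.05 with 24 h minus 12 h. The 12 h minus 0 h difference correlated at 0.28 with 24 h minus 6 h, and 24 h minus 0 h at 0.33 with 12 h minus 6 h. These correlations come from the same arrays and are tied to one another by arithmetic, so the positive values are not separate results. Among 5098 genes with a second probe set above the filter, it pointed the same way as the first for 80.9%, 77.2% and 77.2% of genes at 6, 12 and 24 h. For genes at least 2-fold different the shares were 96.0%, 94.5% and 93.6%. This checks the probes and not the cultures.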

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

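The tests of RNA degradation, of another cell population and of insulin and time as the whole cause were chosen after the results were seen. So was the test of time in culture. Both tests of normalization and the test of a falling share of cells are recorded as set before their own results. The pattern at 24 h against 6 h, however, came from a comparison chosen after the data were seen. Among probe sets without a gene name here, which entered no comparison, 138 were at least 2-fold higher on all 3 insulin arrays than at 0 h and 76 were lower, of 2049 above the filter. Among 560 probe sets with several gene symbols the numbers were 44 and 40. No sample was out of line within its group in a way that can be tested, since each group has 1 array.

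The 0 h array stood apart from the 3 insulin arrays, with 1587 genes at least 2-fold to one side of it at all 3 times. The tables argue against an intensity-dependent trend left by the authors' normalization, since 97.3% of these genes remained after a loess curve was removed and the curve moved no difference from 0 h by more than 0.1199 log2. They argue against RNA degradation, since the 3′ minus 5′ difference of the Actb and Gapdh controls lay within 0.1997 log2 of every insulin array. The medians of whole chromosomes argue against insulin and time as the whole cause. Their standard deviation was 0.173 for the insulin arrays minus 0 h, against at most 0.0411 in 1000 permutations of gene positions. For 24 h minus 6 h it was 0.00837, and 153 of 1000 permutations were as large. The test on Y-linked genes could not decide. It asked for at least 3 of them above the brightness filter, a minimum written after the data were seen. Of the 3 looked at only Eif2s3y passed, and it differed by at least 4.60 log2 at every time. RNA from another cell population went with the same chromosome medians. A candidate explanation is that the 0 h array holds another culture, line or animal, or a wrong label, and any insulin effect inside the difference from 0 h cannot be separated from it with these arrays.

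Bone, cartilage, fat and macrophage genes were higher at 24 h than at 6 h, with a median log2 difference of 0.57 over 52 members of 4 lists. An intensity-dependent trend left by the normalization is argued against, since a loess curve moved no difference by more than 0.0228 and the median was 0.59 after its removal. A falling share of cells like those on the 0 h array would alone raise all genes far above 0 h by a like amount. The 283 other genes 8-fold or more higher at 12 h than at 0 h had a median of only 0.12. For 21 members that were also 8-fold higher the median was 0.72. The ratio was 0.171, with a 95% bootstrap interval over genes of 0.0865 to 0.272. The 4 lists were taken up after their rise was seen, and their medians were the highest of all gene lists at 24 h against 6 h. The ratio can therefore be low in part by selection. It does not decide whether a falling share of cells was the whole cause. The interval leaves out this selection and treats genes on single arrays as independent, so no conclusion is drawn from it. Time in culture without insulin cannot be told apart from insulin, since 0 untreated arrays after 0 h were analysed, and other shifts in the mix of cells may also be involved.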

How the results depend on the processing

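Alternatives added after the data were seen were the insulin arrays as the reference, chromosome medians removed and sex chromosome genes left out. So were further settings for the correlations and the counts of lists. All settings for the 24 h against 6 h counts and list medians were also added then. The others were listed beforehand. Counts of genes against 0 h stayed within 1.5 times under centring, quantile normalization, loess, suffixed probe sets left out, agreement of every probe set, chromosome medians removed and sex chromosome genes left out, and 97.3% of 1587 genes at all 3 times remained after loess, 97.1% after quantile normalization, 85.9% with chromosome medians removed and 71.6% with the mean of all probe sets. Leaving out 1 insulin array gave 1159 to 1245 genes higher and 462 to 502 lower at all remaining times. With the filter at the 75th percentile, which admits fewer genes, 681, 740 and 695 genes were higher at 6, 12 and 24 h, 288, 330 and 295 lower, and 629 higher and 230 lower at all 3 times. At 1.5-fold the numbers were 2170, 2390, 2278 and 1985 higher and 1487, 1553, 1552 and 1225 lower. At 3-fold they were 705, 785, 759 and 667 higher and 169, 188, 172 and 137 lower. With the 6 h array as the reference 3 genes were higher and 2 lower at 12 h, and 50 and 0 at 24 h. With the 12 h array as the reference 1 and 0 were at 24 h. With the 6 h, 12 h or 24 h array as the odd one out the numbers were 0 and 0. For 24 h against 6 h there were 80 higher and 9 lower with the filter at the 75th percentile, 50 and 0 at 2-fold, 29 lower with no brightness filter, and 8 lower with the mean of all probe sets. By Spearman correlation 12 h minus 0 h correlated at 0.18 with 24 h minus 6 h. The counts of lists outside the central 95% of random lists stayed within 1.5 times, and no percentile moved from one side to the other, but percentiles were not computed for means over members. Where the reported median was above that range, 230 of 238 percentiles under the alternatives stayed above it, and where it was below, 126 of 140 stayed below. Where it was inside, 7 of 210 came to lie outside. List medians against 0 h moved by more than the standard deviation of matched random medians as follows. With means over members in place of medians, the values at 6, 12 and 24 h were 0.20, 0.27 and 0.26 (insulin signalling), 2.63, 2.74 and 2.73 (IGF), 0.84, 0.72 and 0.69 (glycolysis), 0.46, 0.49 and 0.47 (immediate early). Further values were 1.05, 1.12 and 1.11 (matrix), 1.81, 2.04 and 2.05 (Wnt), 0.19, 0.38 and 0.36 (inflammatory), 0.65, 1.13 and 1.33 (adipocyte). Those at fewer times were 2.02 and 2.43 (bone, 6 and 24 h), 0.0703 (osteoblast repressor, 6 h), 0.30 (fatty acid, 24 h), 1.75 (BMP, 6 h). Those at fewer times were -1.67 (interferon, 24 h), 0.92 (hypoxia, 6 h), 3.52 and 3.57 (muscle, 6 and 12 h). With the mean of all probe sets of a gene the medians at 6, 12 and 24 h were 1.74, 1.98 and 2.01 (IGF), 1.91, 2.04 and 1.93 (bone), 0.44, 0.29 and 0.31 (glycolysis), 1.27, 1.27 and 1.27 (BMP). Further values were 1.40, 1.74 and 1.95 (macrophage), 4.95, 5.06 and 4.92 (muscle). Those at fewer times were 0.0578 (insulin signalling, 6 h), 0.0959 (osteoblast repressor, 12 h), -0.0515 (fatty acid, 6 h), -0.19 and -0.19 (FoxO, 12 and 24 h). Those at fewer times were -0.52 and -0.96 (mitosis, 6 and 12 h), 0.47 (matrix, 6 h), 0.63 (hypoxia, 24 h). With suffixed probe sets left out they were, at 6, 12 and 24 h, 1.09, 1.04 and 1.05 (IGF), 1.39, 1.89 and 2.30 (bone), 0.79, 0.70 and 0.71 (protease), -0.0889, -0.17 and -0.12 (adipocyte). Further values were 2.93, 3.05 and 2.98 (muscle). Those at fewer times were -0.17 (FoxO, 6 h), -0.50 and -0.72 (inflammatory, 12 and 24 h), 2.08 and 2.65 (macrophage, 6 and 24 h). With no brightness filter they were, at 6, 12 and 24 h, 1.51, 1.74 and 1.81 (bone), 0.83, 0.99 and 0.93 (Wnt), -0.0653, -0.0247 and 0.25 (adipocyte), 1.79, 2.40 and 2.42 (macrophage). Further values were 0.67, 0.51 and 0.54 (muscle). Those at fewer times were 0.0577 (osteoblast repressor, 6 h), -0.033 (FoxO, 6 h), 1.71 (BMP, 12 h), -0.0746 (inflammatory, 6 h). With chromosome medians removed they were, at 6, 12 and 24 h, 0.49, 0.48 and 0.48 (matrix). For 24 h against 6 h the medians were, with no brightness filter, 0.0648 (FoxO), 0.19 (bone) and 0.66 (adipocyte), and with suffixed probe sets left out 0.0993 (FoxO), 0.23 (bone), 0.61 (adipocyte) and -0.26 (hypoxia). With the mean of all probe sets they were 0.50 (macrophage), -0.42 (interferon) and -0.26 (hypoxia), and means over members were 0.41 (bone) and 0.68 (adipocyte). Among lists outside the central 95% of random lists, the inflammatory means at 6, 12 and 24 h and the adipocyte median at 24 h with suffixed probe sets left out turned their sign against 0 h. Among those inside it, the values above turned for insulin signalling at 6 and 12 h with means and at 6 h with the mean of all probe sets, for fatty acid at 6 h with the mean of all probe sets, and for adipocyte at 6 and 12 h with no filter and with suffixed probe sets left out. Further medians inside it turned while moving by less than the standard deviation of random medians. Of 585 values of named genes 102 moved by more than the standard deviation of 24 h minus 12 h differences among genes of like brightness, and none at least 2-fold from 0 h turned its sign. With the mean of all probe sets Col1a1 and Phex at 6 h, which were nearer to 0 h, were -0.23 and -0.30 in place of 0.61 and 0.22. Except where fewer genes or another threshold set the number, the cause was not tested. No paired analysis was possible because each group has 1 array. Leaving out a replicate within a group was not possible for the same reason, and signal over background limits the dim genes.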

Other observations

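All groups in this part were looked at after their values were seen. Of 15 imprinted genes, which are expressed from 1 parental copy and were picked with no fixed list, 8 were at least 2-fold higher on all 3 insulin arrays than at 0 h, 2 were lower and 5 were neither. Meg3 and Dlk1 are neighbours in 1 imprinted cluster. Meg3 had an intensity of 186, 6793, 6596 and 6521 at 0, 6, 12 and 24 h, and Dlk1 had 11384, 674, 693 and 648. Mest was 25.4, 24.9 and 23.2-fold higher at the 3 times, Plagl1 12.7, 12.9 and 12.2-fold, Cdkn1c 25.9, 26.5 and 29.7-fold and Igf2 13.4, 14.6 and 14.8-fold. Rian, another RNA of the Meg3 cluster, was 15.6, 11.5 and 10.0-fold higher. Slc38a4 was 12.5, 14.2 and 13.1-fold lower, and Impact had 1498, 1463, 1475 and 1540.2 on the 4 arrays. The others of the 5 were Snrpn (125, 143, 145 and 129), Igf2r (1786, 1381, 1195 and 1328), Sgce (2007, 1269.9, 1385 and 1193) and Ndn (2722, 5341, 5533 and 4899). Impact and Igf2r each had another probe set above the filter that pointed the other way at some time.

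Of 27 homeobox and other genes tied to position in the body, also picked with no fixed list, 6 were at least 2-fold higher on all 3 insulin arrays, 3 were lower and 18 were neither. Zic1 had 15.04, 1659, 1415 and 1415 at 0, 6, 12 and 24 h. Msx2 was 17.1, 15.9 and 13.9-fold higher on the insulin arrays, Dlx5 8.67, 10.6 and 10.5-fold and Six2 4.22, 4.75 and 4.60-fold. Hoxa7 was 3.33, 3.58 and 3.54-fold lower, Hoxd8 2.65, 2.51 and 2.97-fold and Hoxd9 2.08, 1.86 and 2.41-fold, and the antisense RNA Hoxd3os1 6.20, 5.32 and 6.39-fold lower. Hoxb3 was 1.74, 2.09 and 1.85-fold higher, and Hoxa3 had 102, 101, 102 and 101 on the 4 arrays. Of 12 Hox genes 2 were 2-fold lower at all 3 times and none was higher.

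Some genes far from 0 h lay next to each other. On chromosome 11 a run of 7 measured genes in a row, among them Grb10 and Egfr, was at least 2-fold higher on average over the insulin arrays, and 0 of 200 permuted gene orders held a run as long. On chromosome 6 a run of 4 measured genes was at least 2-fold lower, and 12 of 200 permuted orders held a run of that length, so its length alone does not set it apart. Among its genes were Ndufa9, which had 17547, 3313, 3229 and 3071 at 0, 6, 12 and 24 h, D6Wsu163e and Tigar (732, 114, 117 and 126). Mdm2, which regulates p53 and was in neither run, had 13646, 1895, 1823 and 1865.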
